A study of Homo sapiens with 12 samples.

How the data were processed

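RNA was measured in 12 libraries of H9 human embryonic stem cells, in 4 groups of 3: siNC, siOGA, siP300 and siP300+OGA. Per the labels the libraries were poly(A)-selected, stranded by the dUTP method, tagged with molecular identifiers (UMI) and sequenced as pairs of 150 bases. The submitters' processing notes name cutadapt 1.9, HISAT2 2.0.4, UMI-tools, StringTie 1.3.4d, DESeq2, edgeR and the build GRCh38, without saying what each did. Filters and the strand used in counting are not given in the sources used here, so levels of genes that overlap another gene are uncertain.

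The deposited values are FPKM, made by the authors per kilobase of a listed gene length and per library size, for 62753 genes, of which 1 had its values emptied in the table as given. Every value above 0 was a whole multiple of 1 step per library (100% of values within 0.01 of a whole number), which gave the number of reads, or of fragments, behind each value. These summed to 16238225 to 18714572 per library. The library size implied by the step was 0.935 to 1.06 times that sum, so the authors had scaled the libraries against each other. Recovery was tested on simulated data. Between libraries of a group, the chi-square per degree of freedom was 2.03 to 6.07 over 12 pairs. It was 1.84 to 2.08 for genes with 20 to 199 reads over the pair, and 2.26 to 15.69 with at least 2000. Counting error alone gives a higher value if both reads of a pair were counted than if fragments were. Which were counted is not known, so an excess over counting error is not shown for the genes with few reads.

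Groups were compared with limma 3.58.1 in R 4.3.3 on log2(FPKM + 1), with an intensity trend, all 12 libraries in the model (8 residual degrees of freedom) and a mean of at least 1 FPKM. This left 13166 genes, with 49587 below it. Genes were called at a two-sided Benjamini-Hochberg adjusted p under 0.05 within each of 5 comparisons: siOGA with siNC, siP300 with siNC, siP300+OGA with siP300, siP300+OGA with siNC, and siOGA with siP300. An exact permutation test of 3 against 3 cannot give a two-sided p below 0.1, so none was used for single genes. On simulated data with 200 changed genes of 13166, 95% of changes of 1 and 73% of changes of 0.5 on the log2 scale were found, with 3 false calls. That simulation had few changed genes and independent noise. In the data 48.17% to 74.14% of the tested genes were called, so these rates do not carry over to the counts below. Replicate numbers did not pair the libraries (correlations of deviations from −0.06 to 0.13 over 18 same-numbered pairs), so no block was used.

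The 29 gene lists, the comparisons, the tests and the alternatives were fixed before the data were examined. The 24 lists with at least 5 tested members went through camera with a preset correlation of 0.01, adjusted within each comparison, and the other 5 are given as counts. The lists cover naive, primed and core pluripotency, trophectoderm, hypoblast and endoderm, 8-cell-like, mesoderm, neuroectoderm, amnion and fibroblast genes. They also cover the O-GlcNAc pathway, histone acetylation, p53, interferon, stress, ERK and FGF, WNT, NODAL, BMP, JAK-STAT3, DNA methylation, glycolysis, nuclear oxidative phosphorylation, mitochondrially encoded genes, cholesterol synthesis, S phase, G2 and M phase, heat shock and hypoxia.

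The rule for naming genes was also fixed. It took OGA, EP300, OGT and CREBBP, and the 8 largest rises and 8 largest falls in each of the comparisons of siOGA with siNC, siP300 with siNC and siP300+OGA with siP300. These had to be called, reach a mean of 2 FPKM in the higher group and not overlap between the groups, which chance gives in 10% of genes with 3 against 3. Clone and locus names were excluded. Genes without a symbol and symbols shared by several genes were left out as well, a choice added after the data were seen. The rule added up to 4 members per list, 13 fixed markers and the 8 genes with the largest product of opposite changes. Other genes named, such as list members that moved against their list, genes below the expression minimum and genes of the regions that moved together, were chosen after their values were seen. Some genes that the rule names are not reported here.

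Overlaps between comparisons that share libraries were set against 100 simulations of unchanged groups. After the data were seen, the shared group was also split into 1 and 2 libraries, each part used in 1 of the 2 comparisons, which takes the spread of the single library to be that of the other groups. The alternatives were pseudocounts of 0.1 and 5, no expression minimum or a mean of 5 FPKM, median-ratio and quantile scaling, no intensity trend, sample weights, a fit of only the groups compared, a replicate block, a minimum log2 difference of 1, leaving out each library, camera with an estimated correlation, and fry. Chosen after seeing the data were voom on the recovered reads, the averaging of siP300+OGA replicates 2 and 3 (the most alike pair), and the removal of the median of each 20 Mb region with at least 20 tested genes. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15, with numpy 2.4.6 and pandas 2.3.3.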

Results

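RNA sequencing measured the transcripts of H9 cells, an established human embryonic stem cell line, held in the naive state. Naive cells resemble the pluripotent cells of the early embryo, and primed cells those of a later stage. The growth labels of all 12 samples give PXGL, a medium with inhibitors of MEK, tankyrase and protein kinase C plus the cytokine LIF, on mouse feeder fibroblasts. The sample titles name PXGL too, except those of the group described last below. There were 4 groups of 3 libraries: a control siRNA (siNC), an siRNA against OGA (siOGA), an siRNA against EP300 (siP300), and the EP300 siRNA in cells whose genotype is given as OGA overexpression (labelled siP300+OGA). OGA is the enzyme that removes the sugar O-GlcNAc from proteins, and EP300 is a histone acetyltransferase. The series asks how OGA bears on the pluripotent state. The comparisons below ask what each siRNA changed, what differed between the libraries labelled siP300+OGA and siP300, and what still differed from the control.

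The libraries held 16238225 to 18714572 reads in genes, as recovered from the values, and 1 read per kilobase equalled 0.0518 to 0.0647 FPKM. Levels below are mean FPKM ± SD over 3 libraries. Log2 differences and adjusted p-values come from limma on log2(FPKM + 1), and list tests from camera, for 13166 genes with a mean of at least 1 FPKM. The median SD of a gene between libraries of a group was 0.0804 on the log2 scale. The labels do not say whether the 3 libraries of a group come from separate cultures, so every p-value measures only the spread between these samples.

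OGA (ENSG00000198408, GRCh38 chromosome 10, 101784443 to 101818465, minus strand) stood at 40.5 ± 0.431 in siNC and 8.1 ± 0.771 in siOGA, or 20% of the control (log2 difference −2.19, adjusted p = 2.04e-10). In siP300 it stood at 39.8 ± 1.97, and in the libraries labelled siP300+OGA at 43.8 ± 0.741. That was 110% of siP300 (log2 difference 0.13, adjusted p = 0.0636) and 108% of siNC (0.11, adjusted p = 0.11), so the OGA transcript did not pass the test in the group labelled as overexpressing it. This call depended on the settings. Against siP300 it passed without siOGA replicate 1 (0.13), siOGA replicate 3 (0.13) or siP300 replicate 2 (0.17). It also passed there with a pseudocount of 5 (0.12, adjusted p = 0.0337), in a fit of only the groups compared (0.13, adjusted p = 0.0244) and with voom (0.14, adjusted p = 0.00775). Against siNC it passed without siOGA replicate 3 (0.11), in a fit of only the groups compared (0.11, adjusted p = 0.0094) and with voom (0.11, adjusted p = 0.0253). The construct is not given in the sources used here. EP300 (ENSG00000100393, chromosome 22, 41092592 to 41180077, plus strand) stood at 23.2 ± 0.355 in siNC and 23.5 ± 0.52 in siOGA. It fell to 13.3 ± 0.108 in siP300, 57.2% of the control (log2 difference −0.76, adjusted p = 2e-09). In the libraries labelled siP300+OGA it stood at 15.4 ± 0.329, 66.4% of the control and above siP300 (log2 difference 0.2, adjusted p = 0.000182).

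OGT, the enzyme that adds O-GlcNAc, fell from 57.5 ± 1.31 to 53 ± 2.42 in siOGA (log2 difference −0.12, adjusted p = 0.0106) and to 48 ± 1.01 in siP300 (−0.26, adjusted p = 5e-05). In a fit of only siOGA and siNC the fall in siOGA did not pass (−0.12, adjusted p = 0.0513). CREBBP, the close relative of EP300, rose from 9.88 ± 0.251 to 14.3 ± 0.364 in siP300 (0.49, adjusted p = 1.66e-07) and stood at 16.9 ± 0.384 in the libraries labelled siP300+OGA. With the median of each 20 Mb region removed, the OGA difference between the libraries labelled siP300+OGA and siP300 was 0.37 (adjusted p = 0.000405, against up to adjusted p = 0.751 over the 21 alternatives). OGA in siP300 then stood at −0.21 against siNC (adjusted p = 0.00689), and at 0.15 in the libraries labelled siP300+OGA (adjusted p = 0.0385). The EP300 difference between the libraries labelled siP300+OGA and siP300 shrank to 0.12 and did not pass (adjusted p = 0.0586). That of OGT was then 0.07 in siOGA and 0 in siP300 against siNC.

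**Figure D1:**
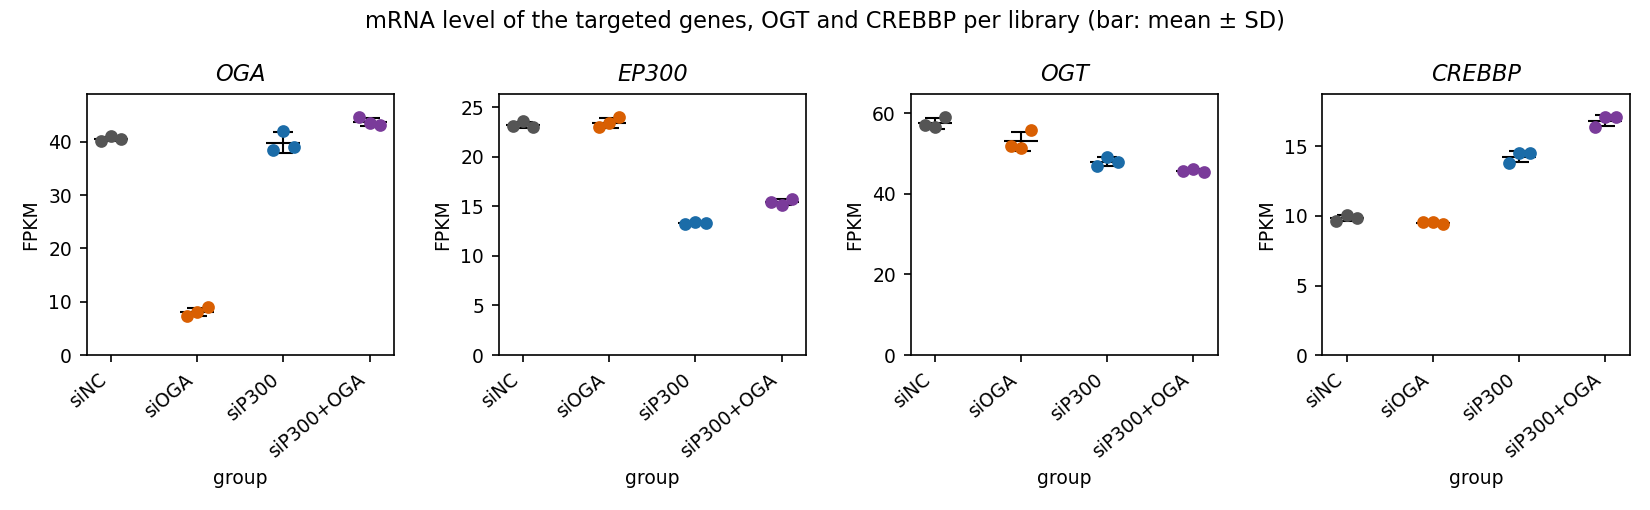
FPKM of OGA, EP300, OGT and CREBBP in each library (points), with the mean and SD of the 3 libraries of a group (bars). OGA falls to 8.1 in siOGA and stands at 43.8 in the libraries labelled siP300+OGA, and EP300 falls to 13.3 in siP300.

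Genes of some chromosome regions moved together, which bears on several genes named below. Over the first 40 Mb of chromosome 10 (96 tested genes), the median change in siP300 against siNC lay 0.53 above that of all genes, with 68 genes higher and 7 lower. In the libraries labelled siP300+OGA against siP300 it lay at −0.58, with 1 gene higher and 82 lower. Relative to the siNC mean, this block stood at 0.49, 0.51 and 0.54 in the 3 siP300 libraries and between −0.06 and 0.07 in the other 9. On chromosome 12, siOGA lay 0.28 to 0.47 above all genes in each 20 Mb region up to 120 Mb. There siP300 lay at −0.33 and −0.41 in the regions from 0 to 40 Mb and at 0.39 from 40 to 60 Mb. The libraries labelled siP300+OGA lay at −0.2, −0.42 and 0.41 against siNC in these regions. From 40 to 60 Mb siOGA stood at 0.42 against siNC but at 0.02 against siP300, so there the siNC libraries stood apart from all others. All tested genes of chromosome 13 (203) and chromosome 15 (375) had medians of −0.24 and −0.23 relative to all genes in the libraries labelled siP300+OGA against siP300. In siOGA against siNC some regions fell, such as the first 20 Mb of chromosome 4 (−0.5, with 7 genes higher and 75 lower). Chromosome 21 from 40 to 60 Mb lay at −0.45 there. All tested genes of chromosomes 9 and 21 had medians of −0.22 and −0.28 in that comparison. The regions in this paragraph were picked out after their values were seen.

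**Figure D2:**
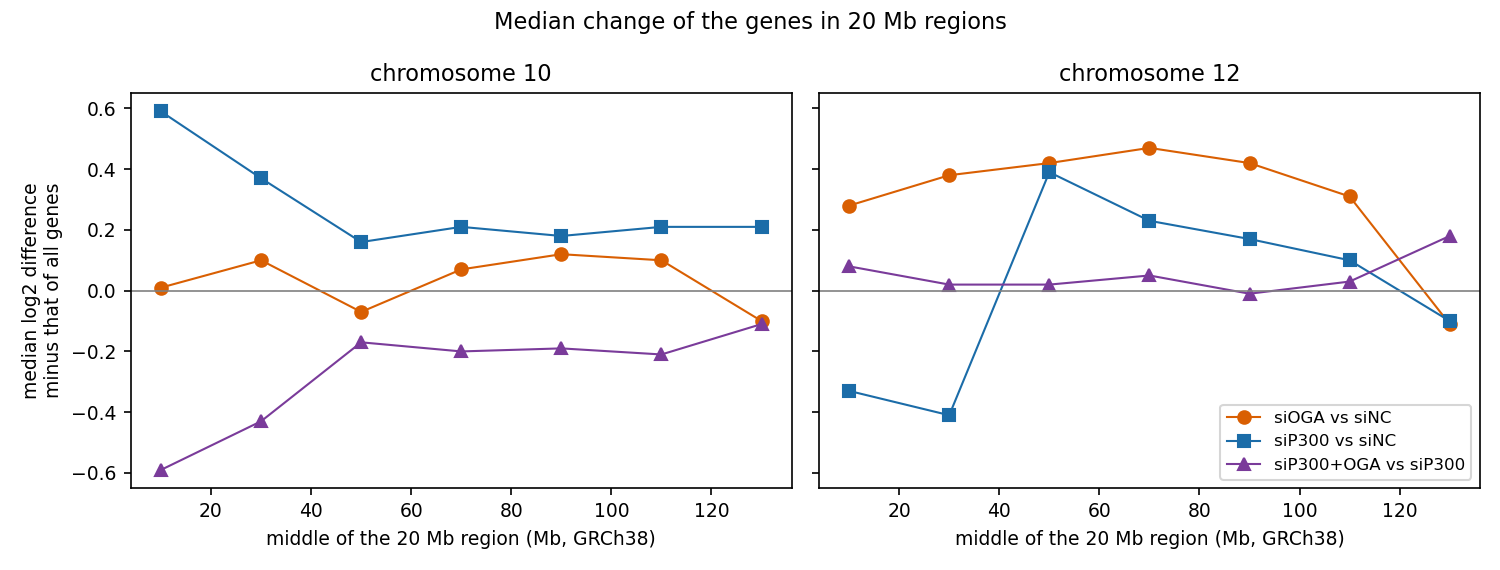
Median log2 difference of the tested genes of each 20 Mb region minus that of all genes (vertical axis) against the middle of the region in Mb (horizontal axis), for chromosomes 10 and 12 and for 3 comparisons. The first regions of chromosome 10 lie at 0.59 and 0.37 in siP300 against siNC and at −0.59 and −0.43 in the libraries labelled siP300+OGA against siP300.

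With the OGA siRNA, markers of the naive state fell and markers of the primed state rose. Among the naive markers, KLF17 fell from 19 ± 0.345 to 2.95 ± 0.34 (log2 difference −2.34, adjusted p = 2.04e-10). DNMT3L, a cofactor of the DNA methyltransferases, fell from 283 ± 15.3 to 98.1 ± 2.51 (−1.52, and −1 with regional medians removed). MAEL, a germline gene, fell from 5.41 ± 0.337 to 0.47 ± 0.182, and DPPA5 from 577 ± 24.9 to 335 ± 37.3 (−0.78). Of 31 tested members of the naive list, 24 fell, 3 rose and 4 did not pass, with the same counts adjusted over the list alone (median −0.71, camera adjusted p = 9.45e-06). DPPA3 stood at 313 ± 10.5 against 291 ± 18.9 and did not pass (0.1, adjusted p = 0.0727), in a region of chromosome 12 whose median rose. With regional medians removed it passed as a fall (−0.22, adjusted p = 0.00436), and it passed as a rise with voom (0.11) and without siNC replicate 3 (0.14) or siOGA replicate 2 (0.13). SUSD2 (−0.12, not passed without an expression minimum, an intensity trend or the other groups, with sample weights, or without siNC replicate 1 or 2, siOGA replicate 1 or 3, or the library labelled siP300+OGA replicate 1) and TFCP2L1 (−0.17, but 0.01 and not passed with regional medians removed) fell by less than the list's median. CPT1A (0.98), DPPA2 (0.61) and KHDC3L (0.4) rose against the list.

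Among the primed markers, the transcription factor ZIC2 rose from 0.68 ± 0.162 to 12.1 ± 0.689 (2.96), the WNT modulator SFRP2 from 0.812 ± 0.274 to 23.7 ± 1.68 (3.78), and the WNT receptor FZD7 from 1.9 ± 0.174 to 21.2 ± 1.29 (2.94). Of 23 tested members, 19 rose and 4 fell, also adjusted over the list alone (median 1.21, camera adjusted p = 9.73e-07). The 4 that fell were OTX2 (−0.5), NLGN4X (−0.78), DNMT3B (−0.72) and SALL3 (−0.48). Core factors shared by both states split. POU5F1 stood at 534 ± 60.2 against 430 ± 23.4 (0.31), SOX2 at 108 ± 7.41 against 93.9 ± 2.28 (0.2) and NANOG at 34.3 ± 1.67 against 44.2 ± 4.55 (−0.35, and −0.68 with regional medians removed). The core list had 5 members higher and 8 lower (camera adjusted p = 0.535). Under quantile normalization POU5F1 turned to −0.05 and SOX2 stood at 0.04, neither past the threshold.

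Genes of cholesterol synthesis rose together in siOGA. HMGCS1 rose from 44.1 ± 1.1 to 172 ± 9.06 (log2 difference 1.94). Of 23 members, 19 rose and 4 fell, also adjusted over the list alone (median 1.09, camera adjusted p = 4.25e-07). The 4 that fell were PMVK, LSS, TM7SF2 and NSDHL. Of 13 ERK and FGF targets, 12 rose and 1 did not pass (median 0.73, adjusted p = 7e-05), with SPRY4 at 2.63 ± 0.0983 against 0.0797 ± 0.0249. DUSP6, the usual marker of ERK activity, stayed under the filter in every group. In a list of fibroblast genes, 8 of 9 rose (median 1.02, adjusted p = 9.54e-05), led by CCN2 (2.16) and FN1 (1.48). Of the fibroblast transcripts ACTA2, COL3A1, DCN, LUM and POSTN, all under the filter, none reached 0.3 FPKM in siOGA, the highest being COL3A1 at 0.207 ± 0.0673.

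NODAL, a growth factor of the pluripotent embryo, fell from 27.2 ± 3.23 to 7.33 ± 1.27 in siOGA, and its targets LEFTY1 and LEFTY2 fell by 2.26 and 2.9. LEFTY1 and LEFTY2 are near-identical, so the counting could have split their reads. Of 12 NODAL and TGF-beta targets, 8 fell and 2 rose (median −0.28, adjusted p = 0.036, and adjusted p = 0.123 with an estimated correlation). Genes of G2 and M phase mostly rose, 15 of 20 against 1 lower (median 0.41, adjusted p = 4.5e-05, and adjusted p = 0.123 with an estimated correlation). The S phase list split into 8 higher and 7 lower, or 8 and 8 adjusted over the list alone (median −0.03, while camera's direction was up, adjusted p = 0.944). The interferon list (8 of 11 higher and 1 lower, adjusted p = 0.0334), the stress and unfolded protein list (15 of 24 higher and 7 lower, adjusted p = 0.029) and the hypoblast and endoderm list (4 of 5 higher, adjusted p = 0.0433) also passed. With an estimated correlation their adjusted p-values were 0.123, 0.123 and 0.136. Most members of the interferon list and of the hypoblast and endoderm list stayed under the filter and were not tested in any comparison. Of the latter, GATA4 (0.176 in siNC and 0.13 in siOGA) and GATA6 (0.0895 and 0.066) had lower means in siOGA. SOX17 (0.04 and 0.24) and APOA1 (0.669 and 2.32) had higher ones. The nuclear oxidative phosphorylation list passed as higher, with 14 of 30 higher, 3 lower and 13 not passed (adjusted p = 0.0342). The DNA methylation list passed as lower, with 7 of 11 lower and 3 higher (adjusted p = 0.0481). These gave adjusted p = 0.347 and adjusted p = 0.235 with an estimated correlation.

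The largest rise in siOGA was that of CCND2, a D-type cyclin, from 0.579 ± 0.0366 to 25.3 ± 0.853 (log2 difference 4.06, adjusted p = 1.75e-11). It lies in the first region of chromosome 12 and stood at 3.74 with regional medians removed. GALNT17 (2.97), ATP6V0D2 (2.71) and PMEL (2.7) were also among the largest rises. The largest falls were those of MIR656, MAGEB2 (−3.04), the long RNA PCAT14 (−3.01), the metallothionein MT1H (−2.99, with close copies among the MT1 genes), LEFTY2, the germline gene GTSF1 (−2.82) and the chemokine receptor CCR8 (−2.35). The pseudogene SUMO1P1 was listed at 0 in all 3 siOGA libraries against 6.7 ± 1.35. MIR656 is a very short gene, at 2.94 ± 2.76 against 27.2 ± 4.22. In all, 4475 genes were higher and 4331 lower in siOGA, of which 443 and 443 changed by at least 1 on the log2 scale. Under quantile normalization the split turned to 4266 higher and 4411 lower. The call for the DNA methylation list did not hold without siNC replicate 2, siP300 replicate 2 or any 1 of the libraries labelled siP300+OGA (adjusted p from 0.0508 to 0.0647), nor that for the oxidative phosphorylation list without siNC replicate 2 (0.0647). With a mean of at least 5 FPKM the ERK (adjusted p = 0.0648), interferon (0.146), stress (0.128), oxidative phosphorylation (0.128) and DNA methylation (0.0674) calls were lost. Under quantile normalization the stress (0.055) and oxidative phosphorylation (0.227) calls were lost, and heat shock genes passed as lower (mean −0.27, adjusted p = 0.0309). With regional medians removed the hypoblast (0.0545) and interferon (0.0536) calls were lost.

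**Figure D3:**
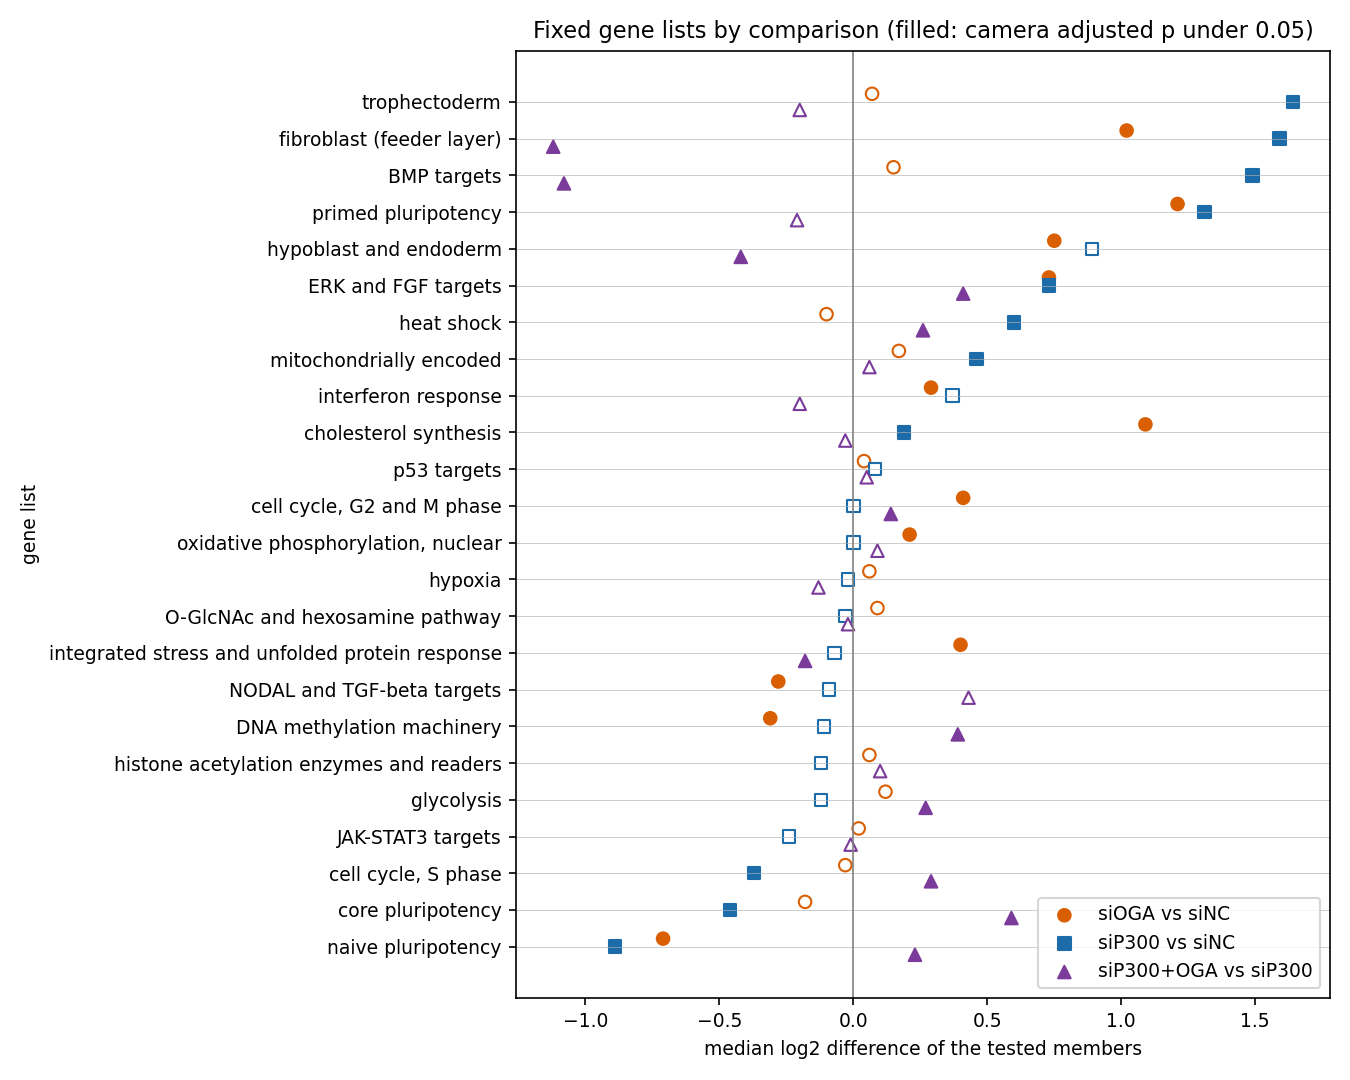
Median log2 difference of the tested members (horizontal axis) of each fixed gene list with at least 5 tested members, for 3 comparisons. Filled points passed camera with a preset correlation, and in siP300 the lists run from a median of 1.64 (trophectoderm) to −0.89 (naive pluripotency).

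With the EP300 siRNA, the largest rises included those of actin genes. ACTC1, cardiac actin, rose from 0.452 ± 0.154 to 151 ± 1.22 (log2 difference 6.71, adjusted p = 6.47e-13), and ACTA1, skeletal actin, from 1.53 ± 0.197 to 99.1 ± 2.01 (5.31). The natriuretic peptide gene NPPB rose to 56.6 ± 2.91 (5.29), calponin CNN1 to 61 ± 1.3 (4.74), the myosin light chain MYL9 to 71 ± 3.44 (4.47), ANKRD1 to 23.5 ± 1.77 (4.36) and transgelin TAGLN to 34.5 ± 1.1 (4.34). The actin genes ACTC1, ACTA1 and ACTG2 share long stretches of sequence, so the counting could have split reads between them. ANKRD1 lies on chromosome 10, whose genes lay 0.24 above all genes, and stood at 4.2 with regional medians removed. In the fibroblast list 7 of 9 rose and 1 fell (median 1.59, adjusted p = 8.56e-05), among them COL1A1 from 1.86 ± 0.116 to 17.5 ± 0.546. Of the fibroblast transcripts ACTA2, COL3A1, DCN, LUM and POSTN, all under the filter, ACTA2 was highest in siP300 at 0.52 ± 0.0965 (0.00667 ± 0.00579 in siNC), and FN1 fell (−0.14).

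BMP targets rose in siP300. The DNA-binding inhibitor ID3 rose from 0.453 ± 0.112 to 25.7 ± 0.94 (4.2), ID2 from 1.08 ± 0.109 to 13 ± 0.43 (2.75) and ID4 from 1.25 ± 0.116 to 10.8 ± 0.101 (2.39). Of 8 tested members 7 rose and 1 did not pass (median 1.49, adjusted p = 2.99e-05). Of 8 tested trophectoderm genes 6 rose and none fell (median 1.64, adjusted p = 0.00151, and adjusted p = 0.0627 with an estimated correlation), including KRT19 from 9.29 ± 0.881 to 96 ± 3.56 and the hormone subunit CGA from 1.14 ± 0.208 to 9.22 ± 0.907. The keratins of this list are expressed in many epithelia. The trophectoderm regulators CDX2, GATA3 and TFAP2A stayed under the filter and were not tested, with means of 0.0593, 0.301 and 0.0321 in siNC and 0.104, 2.21 and 0.277 in siP300. Other untested members with higher means in siP300 included VGLL1 (0.0131 and 0.903), NR2F2 (0.0494 and 0.819) and PGF (0.134 and 1.12).

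Naive markers fell in siP300 as well. NANOG fell from 44.2 ± 4.55 to 12.5 ± 0.394 (−1.74), DPPA3 from 291 ± 18.9 to 74.7 ± 3.34 (−1.95), KLF17 to 6.13 ± 0.239 (−1.49), SUSD2 to 13.5 ± 0.759 (−1.74) and KLF4 to 8.58 ± 0.326 (−1.63). Of 31 naive list members 29 fell, KHDC3L rose (0.82) and NODAL did not pass, also adjusted over the list alone (median −0.89, adjusted p = 6.27e-11). NANOG and DPPA3 lie in the first region of chromosome 12, which fell by 0.33 relative to all genes, and stood at −1.42 and −1.63 with regional medians removed. The core list had 10 lower, 2 higher and 1 not passed (median −0.46, adjusted p = 0.00399), with POU5F1 from 430 ± 23.4 to 278 ± 7.42 (−0.62) and SOX2 to 68.1 ± 0.712 (−0.46, and −0.24 with regional medians removed). Under quantile normalization this list did not pass (mean −0.42, adjusted p = 0.113). Of 23 primed markers 21 rose and 2 fell, also adjusted over the list alone (median 1.31, adjusted p = 5.27e-10). FZD7 rose to 24.3 ± 0.392 (3.13), SFRP2 to 16.8 ± 0.847 (3.31) and the intermediate filament VIM to 15 ± 0.801 (3.11), which is also a mesenchymal marker. VIM lies in the first region of chromosome 10, which lay 0.59 above all genes.

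Genes of S phase fell in siP300, 18 of 19 with none higher (median −0.37, adjusted p = 1.33e-05), such as PCNA from 192 ± 10.2 to 123 ± 4.65. Heat shock genes rose, 8 of 12, or 9 adjusted over the list alone, with none lower (median 0.6, adjusted p = 0.000121), such as HSPB1 from 119 ± 1.26 to 286 ± 11.6. ERK and FGF targets rose in 10 of 13 with 2 lower (median 0.73, adjusted p = 0.00159), but did not pass with a mean of at least 5 FPKM (mean 0.26, adjusted p = 0.547). All of the siP300 calls above held with an estimated correlation (adjusted p from 0.0011 to 0.039) except trophectoderm. Cholesterol synthesis (13 of 23 higher and 3 lower, adjusted p = 0.00522) and the mitochondrially encoded genes (8 of 13 higher and none lower, adjusted p = 0.00186) passed too, with adjusted p = 0.0627 and adjusted p = 0.378 with an estimated correlation. Under quantile normalization the mean of the mitochondrial list turned to −0.03.

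The largest falls in siP300 were those of GTSF1 (−2.81), FXYD4 (−2.72), the cannabinoid receptor CNR2 (−2.66), the small nuclear RNA pseudogene RNU7-75P (−2.6), the parathyroid hormone receptor PTH1R (−2.53), GDPD2 (−2.53), MT1H (−2.44) and MAGEB2 (−2.4). RNU7-75P stood at 0.602 ± 1.04 in siP300 against 8.99 ± 5.86 in siNC, a wide spread between libraries. In the hexosamine pathway GFPT1, its rate-limiting enzyme, fell from 117 ± 4.95 to 42.9 ± 1.27 (−1.43), while the list split into 6 higher and 5 lower (median −0.03, adjusted p = 0.876). In all, 3975 genes were higher and 4697 lower in siP300, of which 608 and 391 changed by at least 1 on the log2 scale. The split was 4340 and 4289 under median-ratio scaling, 5709 and 5420 without an expression minimum, and 2023 and 3149 with a mean of at least 5 FPKM.

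**Figure D4:**
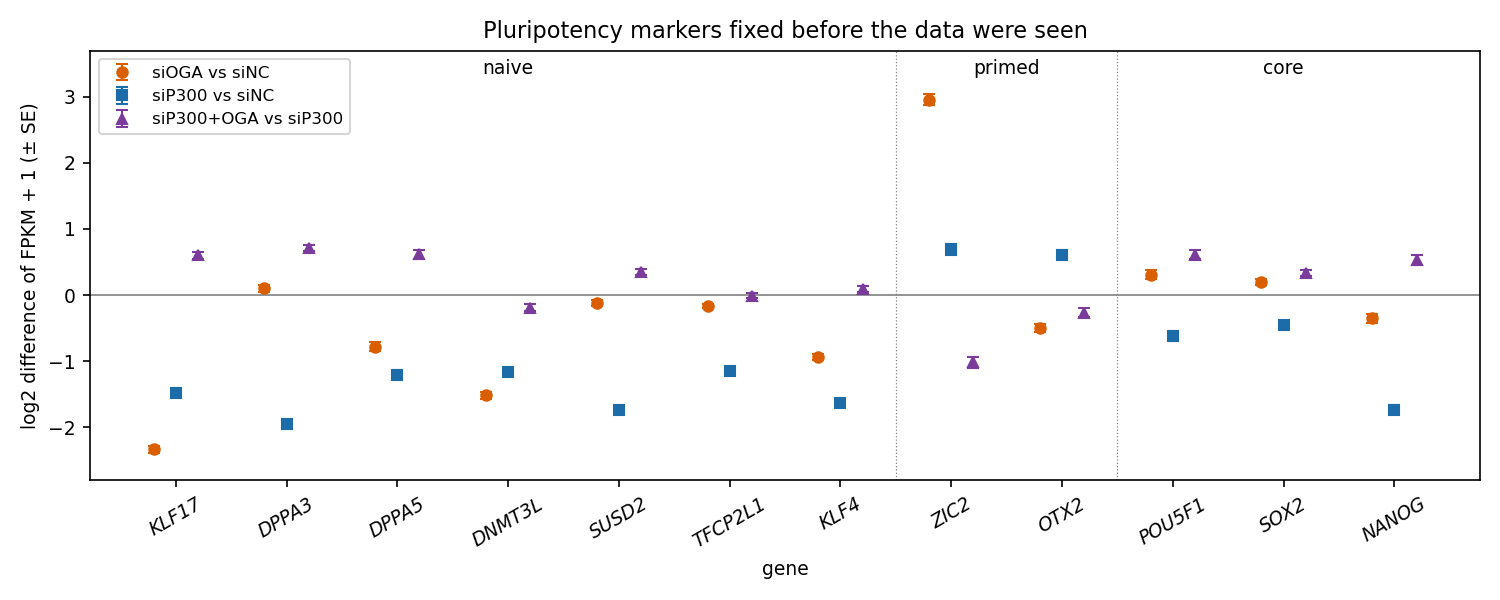
Log2 difference (± SE, vertical axis) of the fixed naive, primed and core markers that passed the expression filter, for 3 comparisons. KLF17, DPPA5, DNMT3L and KLF4 lie below 0 in both knockdowns, and DPPA3 lies at −1.95 in siP300 and 0.1 in siOGA.

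In the libraries labelled siP300+OGA, several of the genes that rose most in siP300 stood far below it. ACTC1 fell from 151 ± 1.22 to 1.64 ± 0.191 (log2 difference −5.85, adjusted p = 4.73e-12), NPPB to 0.817 ± 0.28 (−5), ANKRD1 to 0.28 ± 0.107 (−4.26), CNN1 to 4.43 ± 0.159 (−3.52), TAGLN to 2.56 ± 0.0747 (−3.32) and ACTA1 to 11 ± 0.548 (−3.06). CGA (−3.27) and VIM (−3.04) completed the largest falls, and VIM stood at −2.4 with regional medians removed. In the fibroblast list 8 of 9 fell (median −1.12, adjusted p = 5.56e-08). All 8 BMP targets fell (median −1.08, adjusted p = 1.87e-06), with ID3 from 25.7 ± 0.94 to 8.65 ± 0.61. Among the 8, BAMBI lies in the block of chromosome 10 and turned from −0.27 to 0.18 with regional medians removed. Without siP300 replicate 3 or the library labelled siP300+OGA replicate 1 it stood at −0.22 and did not pass.

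All 13 core pluripotency genes rose in the libraries labelled siP300+OGA against siP300 (median 0.59, adjusted p = 3.86e-09). POU5F1 rose from 278 ± 7.42 to 427 ± 6.13 (0.61), SOX2 from 68.1 ± 0.712 to 85.7 ± 1.86 (0.33, and 0.22 with regional medians removed), NANOG from 12.5 ± 0.394 to 18.5 ± 1.17 (0.53) and UTF1 from 141 ± 8.37 to 300 ± 9.97 (1.09). Of 19 S phase genes 17 rose and none fell (median 0.29, adjusted p = 2.25e-06). With an estimated correlation, the fibroblast, BMP, core and S phase calls held (adjusted p from 0.0034 to 0.00852). Naive markers split. Of 31, 18 rose, 6 fell and 7 did not pass, with 9 lower adjusted over the list alone (median 0.23, adjusted p = 0.0491, and adjusted p = 0.119 with an estimated correlation). KLF17 (0.6), DPPA3 (0.71), DPPA5 (0.62) and GDF3 (0.95) rose, while OLAH (−2.25), the near-identical alkaline phosphatases ALPG (−1.52) and ALPP (−1.41), KLF5 (−0.81) and DNMT3L (−0.19, and −0.31 with regional medians removed) fell. KLF4 (0.09, adjusted p = 0.132) and TFCP2L1 (−0.01, adjusted p = 0.822) did not pass, though TFCP2L1 passed as lower with regional medians removed (−0.11, adjusted p = 0.0199). OLAH lies in the first region of chromosome 10 and stood at −1.61 with regional medians removed. Primed markers split into 7 higher and 14 lower (median −0.21, adjusted p = 0.0903), and passed as lower under quantile normalization (adjusted p = 0.0326).

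The largest rises there were those of TIMP4, an inhibitor of matrix proteases, from 6.04 ± 1.29 to 32.4 ± 0.868 (2.26), the ERK-responsive factor ETV4 from 7.82 ± 0.118 to 33.6 ± 1.13 (1.97), HOXB1 (1.96), FGF19 (1.72), the metallothioneins MT2A (1.64) and MT1H (1.57), CASQ1 (1.58) and PCAT14 (1.54). The 4 tested WNT targets all rose: SP5 (1.14), AXIN2 (0.98), TCF7 (0.8) and ZNRF3 (0.48), too few for a list test. DNA methylation genes rose in 7 of 11 with 2 lower (adjusted p = 0.0108), with DNMT3B from 160 ± 2.13 to 350 ± 3.92, and heat shock genes in 9 of 12 with 1 lower (adjusted p = 0.00427). Stress and unfolded protein genes fell in 16 of 24 with 5 higher (adjusted p = 0.00534). With an estimated correlation these gave adjusted p = 0.119, adjusted p = 0.118 and adjusted p = 0.0936. ERK and FGF targets (9 of 13 higher and 3 lower, adjusted p = 0.0246), glycolysis (13 of 21 higher and 3 lower, or 14 and 4 adjusted over the list alone, adjusted p = 0.0246), G2 and M phase (12 of 20 higher and 4 lower, adjusted p = 0.0449) and hypoblast and endoderm (4 of 5 lower and none higher, adjusted p = 0.0246) passed as well. With an estimated correlation their adjusted p-values were 0.0965, 0.302, 0.325 and 0.118.

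In all, 3556 genes were higher and 2786 lower in the libraries labelled siP300+OGA against siP300, of which 56 and 181 changed by at least 1 on the log2 scale. With a mean of at least 5 FPKM the split was 2753 higher and 1386 lower, but it turned to 3068 and 3149 under median-ratio scaling and to 3298 and 3534 without an expression minimum. The naive list call did not hold without siNC replicate 1 or 3, siOGA replicate 3, siP300 replicate 1 or 2, or the libraries labelled siP300+OGA replicate 2 or 3 (adjusted p from 0.05 to 0.0756), nor with regional medians removed (0.0678), a replicate block (0.0723), quantile normalization (0.155) or a mean of at least 5 FPKM (0.343). The G2 and M phase call did not hold without siNC replicate 1, siP300 replicate 1 or the library labelled siP300+OGA replicate 2 (adjusted p from 0.0543 to 0.0613), nor under median-ratio scaling (0.059), quantile normalization (0.831) or a mean of at least 5 FPKM (0.328). The glycolysis call was lost under quantile normalization (0.314) and a mean of at least 5 FPKM (0.328). The heat shock (0.155) and DNA methylation (0.0697) calls were lost under quantile normalization, and the hypoblast call with regional medians removed (0.0673).

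Of 8672 genes called in siP300 against siNC, 3962 were called the opposite way in the libraries labelled siP300+OGA against siP300, and 938 the same way. Of 3975 genes higher in siP300, 1757 fell, and of 4697 lower genes 2205 rose. Independent lists of these sizes would share 841 and 1269. The counts include genes of regions that moved together. On chromosomes 10, 13 and 15, 241, 83 and 172 genes were higher in siP300 against siNC and 86, 36 and 69 lower. In the libraries labelled siP300+OGA against siP300, 34, 9 and 13 genes of these chromosomes were higher and 251, 114 and 200 lower. Both comparisons use the siP300 libraries. Simulations in which no group differed gave a mean of 0 and 0.01 such genes. Almost no gene is called in them at all, so these counts cannot show what the shared libraries add. Across genes, which are not independent replicates, the changes correlated at −0.557 (simulated −0.499, from −0.555 to −0.442), with a covariance of −0.121 against −0.00982, a difference of −0.111. The 3 siP300 libraries were also split into 1 and 2, each part used in 1 comparison (6 ways, chosen after the data were seen). The correlation then ran from −0.497 to −0.475. Higher genes that fell numbered 1258 to 1467 (independent lists 533 to 628), and lower genes that rose 1472 to 1750 (794 to 925). A difference common to all 3 siP300 libraries would still enter both comparisons. Of 999 genes that changed by at least 1 in siP300, 652 reversed, 61 moved further and 286 did not pass. The median reversal among these 999 was 32.6% of the siP300 change (quartiles 10.5% and 56.1%), and 884 still differed from siNC. It was 41.5% for the 608 higher genes, of which 452 reversed, and 22.6% for the 391 lower genes, of which 200 reversed.

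The 8 genes with the largest opposite changes were ACTC1, NPPB, ANKRD1, CNN1, ACTA1, TAGLN, MYL9 and ACTG2. In the libraries labelled siP300+OGA, NPPB (0.29, adjusted p = 0.0827) and ANKRD1 (0.1, adjusted p = 0.387) did not pass against siNC. ACTA1 (2.25), MYL9 (1.96), ACTG2 (1.63), CNN1 (1.23), TAGLN (1.03) and ACTC1 (0.86) stayed higher. Without the library labelled siP300+OGA replicate 2 or without siOGA replicate 1, NPPB passed (0.42, adjusted p = 0.0166, and 0.29, adjusted p = 0.043). POU5F1 did not differ detectably from siNC (−0.01, adjusted p = 0.924). NANOG (−1.21), DPPA3 (−1.24), KLF17 (−0.89) and KLF4 (−1.54) stayed lower.

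**Figure D5:**
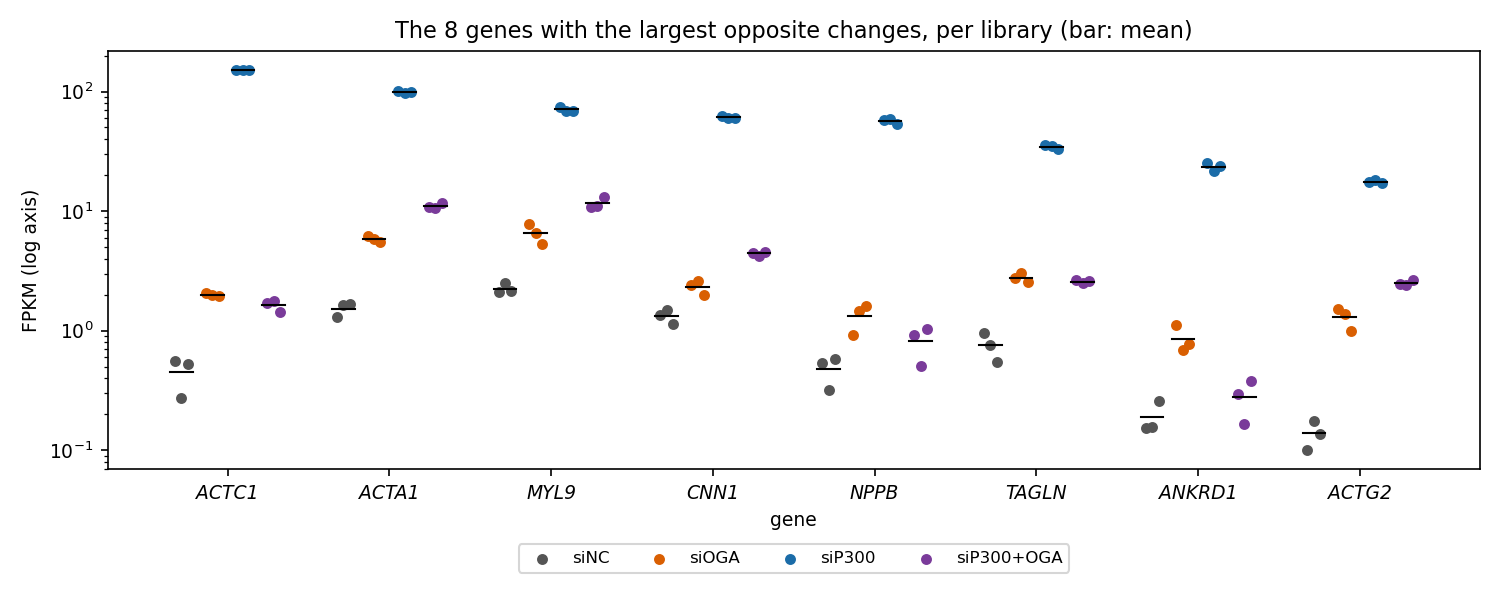
FPKM per library (points, logarithmic axis) and group mean (bars) of the 8 genes with the largest opposite changes in siP300 against siNC and in the libraries labelled siP300+OGA against siP300. ACTC1 stands at 0.452 in siNC, 151 in siP300 and 1.64 in the libraries labelled siP300+OGA.

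Against siNC, the libraries labelled siP300+OGA had 4052 genes higher and 3970 lower, of which 327 and 329 changed by at least 1 (2349 higher and 2435 lower with a mean of at least 5 FPKM). Of 31 naive markers 29 were lower and 2 higher (median −1.03, adjusted p = 9.13e-12), and of 23 primed markers 18 were higher and 3 lower (median 0.64, adjusted p = 8.57e-08). The core list had 7 higher and 5 lower (median 0.22, adjusted p = 0.456). All 12 heat shock genes were higher (median 0.66, adjusted p = 8.57e-08), and ERK and FGF targets were higher in 10 of 13 with none lower, or 1 adjusted over the list alone (median 1.21, adjusted p = 1.97e-05). The naive, primed, heat shock and ERK calls held with an estimated correlation (adjusted p from 0.0017 to 0.0145). The mitochondrially encoded genes (11 of 13 higher and none lower, adjusted p = 0.000697), BMP targets (4 of 8 higher and none lower, adjusted p = 0.0128), cholesterol synthesis (11 of 23 higher and 1 lower, adjusted p = 0.0215) and stress genes (15 of 24 lower and 4 higher, adjusted p = 0.00933) passed with the preset correlation but not with an estimated one. With an estimated correlation their adjusted p-values were 0.344, 0.0819, 0.146 and 0.0981.

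The knockdowns were also compared with each other, which uses no shared control. Between siOGA and siP300, 5178 genes were higher and 4583 lower in siOGA, against 4788 and 4901 under median-ratio scaling 6417 and 6725 without an expression minimum, and 3379 and 2206 with a mean of at least 5 FPKM. BMP targets were lower in siOGA in 7 of 8 (median −1.33, adjusted p = 0.000937), cholesterol synthesis genes higher in 19 of 23 with 3 lower (median 0.79, adjusted p = 0.000508) and S phase genes higher in 15 of 19 with 1 lower (median 0.32, adjusted p = 0.00189). All 3 held with an estimated correlation at adjusted p = 0.0411. Primed markers had no common direction, with 10 higher, 11 lower and 2 not passed (median 0.01, mean −0.06, adjusted p = 0.699). Of the ERK and FGF targets 6 were higher and 5 lower (median 0.04, adjusted p = 0.928). The naive list passed as higher in siOGA, with 17 of 31 higher and 6 lower (median 0.2, adjusted p = 0.0298, and adjusted p = 0.113 with an estimated correlation). Heat shock genes were lower in 8 of 12 with 2 higher (median −1, adjusted p = 0.0036, and adjusted p = 0.113 with an estimated correlation).

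Relative to siNC, both siRNAs raised 1894 genes and both lowered 2021, where independent lists would share 1351 and 1545. Opposite calls numbered 1299 (up in siOGA and down in siP300) and 1008 (the reverse), where independent lists would share 1596 and 1308. The changes correlated across genes at 0.316. Simulations in which no group differed, with 1 simulated control in both comparisons, gave 0.497. Their covariance was 0.00983 against 0.102 observed, a difference of 0.0924. With the siNC libraries split in the same way, the correlation ran from 0.261 to 0.287. Then 1539 to 1595 genes were raised by both siRNAs (independent lists 1032 to 1092) and 1588 to 1638 lowered by both (1174 to 1226). A difference common to all 3 siNC libraries would still enter both comparisons. On chromosome 12 from 40 to 60 Mb, siOGA lay 0.42 and siP300 0.39 above siNC, relative to all genes.

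The remaining fixed lists did not pass camera in the 3 main comparisons. In siOGA, siP300 and the libraries labelled siP300+OGA against siP300, the camera adjusted p-values were 0.493, 0.236 and 0.285 for p53 targets, 0.774, 0.876 and 0.528 for hypoxia, and 0.832, 0.348 and 0.285 for JAK-STAT3 targets. With a mean of at least 5 FPKM, JAK-STAT3 targets passed as lower in siP300 (mean −0.82, adjusted p = 0.0175), and NODAL targets as higher in the libraries labelled siP300+OGA against siP300 (mean 0.54, adjusted p = 0.0193). In the latter comparison cholesterol synthesis passed as lower under quantile normalization (mean −0.12, adjusted p = 0.0302), and nuclear oxidative phosphorylation as higher with regional medians removed (mean 0.12, adjusted p = 0.0206). They were 0.521, 0.638 and 0.185 for histone acetylation enzymes and readers, and 0.663, 0.876 and 0.689 for the O-GlcNAc and hexosamine pathway. Glycolysis gave 0.309 in siOGA and 0.614 in siP300, trophectoderm 0.493 in siOGA, and BMP targets 0.178 there. Medians and means differed in sign for the O-GlcNAc list in siOGA (0.09 and −0.21), NODAL targets in siP300 (−0.09 and 0.08) and in the libraries labelled siP300+OGA against siP300 (0.43 and −0.01), and p53 targets in the latter (0.05 and −0.16). Lists with too few tested members for a test were 8-cell-like (3 of 3 lower in siOGA), mesoderm (2 of 4 higher and 1 lower), neuroectoderm (1 of 2 higher, the other not passed), amnion (2 of 4 higher and 1 lower) and WNT targets (3 of 4 lower). Among them the receptor KDR rose from 1.8 ± 0.116 to 13.5 ± 0.834 in siOGA, and NES rose from 20.5 ± 1.07 to 108 ± 3.39 in siP300.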

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

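Among the tests below, those of feeder RNA, of a random draw of genes on chromosome 12, of RNA without poly(A) tails, of mitochondrial mRNA and of the reversal with regional medians removed were chosen only after the result was seen, as was the block at the start of chromosome 10 itself.

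For 3 of 16 fixed genes the 2 knockdowns moved in opposite directions from the control, and the test of the difference passed. Among all 13166 tested genes, 1299 were called up in siOGA and down in siP300, and 1008 the reverse. Opposite calls were therefore not particular to the fixed genes. OTX2 fell in siOGA (−0.5) and rose in siP300 (0.61), a difference of −1.12 (adjusted p = 5.39e-08). POU5F1 rose in siOGA (0.31) and fell in siP300 (−0.62), a difference of 0.93 (adjusted p = 3.47e-07). SOX2 rose in siOGA (0.2) and fell in siP300 (−0.46), a difference of 0.66 (adjusted p = 1.3e-07). Under quantile normalization the differences were −1.09, 0.52 and 0.36, but POU5F1 stood at −0.05 and SOX2 at 0.04 in siOGA against siNC.

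For each of the 5 counts of changed genes, the 6 libraries compared make 10 splits into 3 and 3, too few for a share under 0.05. In each comparison 1 of the 10 splits gave as many genes, which was the real split, and the highest of the other splits gave 0. The other splits mix libraries of both groups, so a difference between the groups widens the spread within each part. Their 0 is therefore no support for the real counts. The real counts were 8806 (siOGA with siNC), 8672 (siP300 with siNC), 6342 (siP300+OGA with siP300), 8022 (siP300+OGA with siNC) and 9761 (siOGA with siP300).

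The partial reversal of the siP300 changes in the libraries labelled siP300+OGA could come from a weaker EP300 knockdown, since EP300 itself reversed by 26.3% (SE 3.38). That rests on a rise of 0.2 (SE 0.0287) over siP300, which shrank to 0.12 (SE 0.0452) and did not pass with regional medians removed, as the median of EP300's own region was taken out. A shrinkage of every response by that factor is argued against, because 35.4% of the 999 genes lay within 2 standard errors of it, with 398 above and 247 below. With regional medians removed EP300 reversed by 16.7% (SE 6.09), and 41.5% of 957 genes lay within 2 standard errors, with 443 above and 117 below. Whether RNA of the mouse feeder fibroblasts in the siP300 libraries adds to large rises such as that of ACTC1 (151 FPKM) is not decided. The highest of 5 transcripts abundant in fibroblasts was ACTA2 at 0.52 ± 0.0965 FPKM, and FN1 fell. In the other direction, ACTA2 rose from 0.00667, COL1A1 from 1.86 to 17.5 and COL1A2 from 3.05 to 12.7, and 7 of 9 tested fibroblast genes rose. All of these are values of human genes, and how much mouse RNA the counting would take for human was not tested. A gene-specific response to a weaker knockdown, an effect of the OGA overexpression that the labels give and a difference between the cultures stay open. The OGA transcript stood 0.13 above siP300 without passing, and at 0.37, past the threshold, with regional medians removed. Most of the latter came from a lower siP300, which then stood at −0.21 against siNC, while siP300+OGA stood at 0.15.

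Whole chromosome regions shifted between groups. A trend with GC content or gene length is argued against for chromosome 12 in siOGA, whose median stood at 0.27 above all genes after regression on both (0.29 before). Of 10000 random gene sets matched on mean expression alone, 0 lay as far from the median of all genes. Chromosome 12 had the largest shift of all chromosomes in this comparison, and the draws treated neighbouring genes as independent. That count therefore adds no support. A difference in copy number between the cultures stays open for both regions. At the start of chromosome 10 all 3 expression tertiles were lower in siP300+OGA against siP300, the highest median being −0.65. That block was chosen for being lower there, so its tertiles decide nothing. On chromosome 12, 6 of 7 regions of siOGA lay above all genes. From 40 to 60 Mb siP300 (0.39) and siP300+OGA (0.41) lay about as far above siNC as siOGA (0.42). There siOGA stood at 0.02 against siP300, so the shift of that region is not particular to siOGA. Regulation over long stretches was not tested, and DNA copy number was not analysed here.

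The mitochondrial 16S rRNA MT-RNR2 rose from 2390 ± 225 FPKM in siNC to 9280 ± 462 in siOGA (1.96), and stood at 5620 ± 177 in siP300 (1.24). Under quantile normalization these rises were 1.48 and 0.46. The other mitochondrial rRNA, MT-RNR1, rose less, from 384 ± 93.3 to 636 ± 65 in siOGA (0.75, adjusted p = 0.00112) and 577 ± 31.2 in siP300 (0.62, adjusted p = 0.00405). As a set, 191 nuclear RNAs without poly(A) tails did not rise in siOGA (median 0.02, SD 0.78). Most of them were snRNAs (84) and snoRNAs (86), which are short, with 19 histone genes. They cannot show whether long RNAs without poly(A) tails, such as rRNA, were carried over, so that stays open. More mitochondrial RNA per library is argued against, since the 13 mitochondrial mRNAs had a median of 0.17 (SD 0.45). A change in the tailing or priming of these rRNAs, or in their amount, may lie behind it and was not tested.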

How the results depend on the processing

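The alternatives chosen only after the data were seen were voom, the averaging of siP300+OGA replicates 2 and 3, the removal of regional medians, and separate control libraries for comparisons that share a group. No level of OGA or EP300 and no correlation among the main results reversed under any of the alternatives run. For levels, a change of sign between values that both did not pass was not counted as a reversal. Main results that are counts could only stay or move, so a reversal was not possible for them. Their split into higher and lower genes did turn under some settings, as given above. Of the values of all main results, 406 kept their side of the threshold without a reversal (or moved little), 27 moved, 13 gained a call and 1 lost it. Among 393 results for named genes, 32 changed in some way. Where no cause is given, the cause was not tested.

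With a mean of at least 5 FPKM, which tests fewer genes, the counts were 5117, 5172, 4139, 4784 and 5585 in the 5 comparisons in the order given above, 2625 siP300 calls were reversed, 6 lists changed in siOGA and the correlation of siOGA with siP300 changes was 0.323. With a log2 difference of at least 1, the counts were 886, 999, 237, 656 and 1516. That correlation was 0.333 under quantile normalization, 0.33 with voom, 0.278 with separate control libraries (median of 6 ways), 0.326 with regional medians removed and 0.305 to 0.327 without single libraries. With an estimated correlation 5 lists changed in siOGA and 4 in siP300+OGA against siP300. With fry, which does not compare a list with other genes, 22, 21 and 21 changed in siOGA, siP300 and siP300+OGA against siP300.

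OGA in siP300+OGA against siP300 moved to 0.12 (pseudocount of 5), 0.13 (only the groups compared), 0.14 (voom) and 0.37 (regional medians removed), all past the threshold, and ran from 0.11 to 0.17 without single libraries. It passed without siOGA replicate 1 (0.13), siOGA replicate 3 (0.13) or siP300 replicate 2 (0.17). Against siNC it passed at 0.11 (only the groups compared), 0.11 (voom), 0.15 (regional medians removed) and 0.11 (without siOGA replicate 3), and ran from 0.09 to 0.12 without single libraries. With regional medians removed, OGA in siP300 against siNC passed at −0.21, and EP300 passed at 0.13 in siOGA against siNC and did not pass at 0.12 in siP300+OGA against siP300 (adjusted p = 0.0586, against as low as adjusted p = 5.17e-05 over its 21 alternatives). These removals take out the median of the gene's own region, by construction.

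Under quantile normalization the mitochondrially encoded list in siP300 reversed to a mean of −0.03, MT-CYB to −0.19 and MT-ND6 to −0.1 there, POU5F1 in siOGA to −0.05, and OGT in siOGA against siP300 to −0.08. With regional medians removed, OGT reversed to 0.07 in siOGA and 0 in siP300, DPPA3 to −0.22 and TFCP2L1 to 0.01 in siOGA, and BAMBI to 0.18, ATP5F1C to 0.04 and IDI1 to 0.1 in siP300+OGA against siP300. Without single libraries the counts ran from 8230 to 8744, 8129 to 8897, 5570 to 6717, 7393 to 8293 and 9270 to 9741.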

Other observations

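The test of gene families by name was chosen only after the data were seen. Of 205 families 4, 2 and 14 changed in siOGA, siP300 and siP300+OGA against siP300 with a preset correlation, and 0 did with an estimated correlation. The 8 tested metallothioneins, whose copies are alike enough that the counting can split their reads, all fell in siOGA (median −1.36, adjusted p = 0.0263, and adjusted p = 0.815 with an estimated correlation). In siP300 against siNC all 8 were lower too, from −0.75 (MT1E) to −2.44 (MT1H), though the family was not among the 2 that changed there. All 8 rose in siP300+OGA against siP300 (median 1.33, adjusted p = 0.00331, and adjusted p = 0.542 with an estimated correlation). ZNF genes fell in siOGA in 238 of 441, with 53 higher (median −0.23, adjusted p = 1.73e-05, and adjusted p = 0.771 with an estimated correlation).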
